A study of Mus musculus and Homo sapiens with 7 samples.

How the data were processed

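Gastric corpus tissue was profiled by droplet single-cell RNA sequencing in 7 libraries. In 2 libraries the tissue came from C57BL/6 mice chronically infected with Helicobacter pylori strain PMSS1 (Hp, 1 female library labelled 13MOI and 1 male library labelled 6MOI). In 2 libraries it came from TxA23 mice (1 female and 1 male library, both labelled 5MOA), a T cell receptor transgenic line with autoimmune gastritis, labelled as crossed to B6.C H2-d/b (TxA23 Thy1.2/1.2). In 3 libraries it came from patients with autoimmune gastritis (AIG). Per the labels' protocols, each mouse library pooled the corpora of 2 to 7 mice, the tissue was digested with collagenase and trypsin at 37 degrees, and libraries were made with the Chromium 5′ kit v2. A mouse replicate here is therefore a pool, and the p-values measure the spread between these libraries. Reading from the 5′ end captures the variable parts of antigen receptor transcripts.

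The deposited values were raw counts of unique molecular identifiers (UMIs) per gene and cell, made with Cell Ranger, per the file headers version 6.0.2 for the mouse libraries, 6.1.1 for AIG replicates 1 and 2 and 7.1.0 for AIG replicate 3. The genome builds were mm10 (GRCm38) and GRCh38, and Seurat was also used, per the submitters' processing notes. Whether intron reads were counted is not given in the sources used here. The matrices held only barcodes that the authors had called as cells. Total counts per library were 126006649 and 219338427 UMIs for Hp replicates 1 and 2, 79688027 and 56613120 for TxA23 replicates 1 and 2, and 35711469, 27864616 and 101606480 for AIG replicates 1 to 3. The barcodes of Hp replicate 2 came from 6 wells and those of each other library from 1. Gene positions are 1-based GRCm38 coordinates. No human annotation was used, so human genes are named by symbol and identifier only.

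Cells with at least 300 genes and 500 UMIs and at most 25% mitochondrial UMIs were kept. Scrublet (scanpy 1.11.5, expected doublet rate 0.08) scored doublets in each library. Its automatic threshold marked under 0.5% of the cells in 6 of the 7 libraries and was judged not to have worked, so the barcodes with the highest scores were removed at a rate of 0.8% per 1000 barcodes in each well. This departs from the plan, and keeping all doublets was an alternative. The cells kept numbered 6370 and 14118 in Hp, 6550 and 6128 in TxA23, and 3179, 2336 and 8575 in AIG.

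For each species, counts were scaled to 10000 per cell and log-transformed, 2000 variable genes were chosen with library as batch, and 30 principal components, 15 neighbours and Leiden resolution 1.0 gave the clusters, with no integration of libraries. A cluster was named from fixed marker lists when at least 3 markers of the best-scoring class were at least 2-fold higher than elsewhere and its 10 leading genes held no more markers of another class than of its own. Other clusters stayed unnamed. The classes compared were metaplastic-like cells (Muc6, Tff2, Gkn3, Aqp5, Cftr, Clu, Wfdc2, Dmbt1, Cd44, Gpx2, Wfdc18, Glipr1), which overlap with mucous neck cells and with spasmolytic polypeptide-expressing metaplasia (SPEM), surface mucous or pit-like cells (Muc5ac, Gkn1, Gkn2, Tff1, Psca and others), T cells and B cells. The metaplastic-like list given is that of the mouse. The human list kept MUC6, TFF2, AQP5, CFTR, CLU, WFDC2, DMBT1 and CD44 and held OLFM4, LYZ, PRR4 and BPIFB1 in place of the others. The class therefore had partly different markers in AIG than in the mice. The shares of cells are percentages of the cells kept, with Wilson 95% intervals that cover counting error only.

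UMIs were summed per library and class where a class had at least 25 cells in each library, and the sums were tested, since cells are not replicates. The main test was edgeR 4.0.16 (R 4.3.3; TMM scaling, filterByExpr, glmQLFit and glmQLFTest, two-sided, Benjamini-Hochberg adjusted p under 0.05). Hp was compared with TxA23 in metaplastic-like, pit-like, T and B cells. Metaplastic-like cells were compared with pit-like cells within Hp, TxA23 and AIG with the library as a block, because both classes came from the same tissue, and the difference of this contrast between Hp and TxA23 was tested as an interaction. Classes were taken from the same counts, so the p-values of the class contrasts are too small. The standard error of a log2 fold was its size divided by the square root of the F statistic. Fixed gene lists were tested with camera (limma 3.58.1, correlation preset at 0.01, and again with an estimated correlation) and with fry, adjusted over 19 lists in metaplastic-like cells and 14 in T cells. Mouse and human genes were matched by symbol, 10098 in all. T cell receptor use was the share of T cells whose most abundant V gene was a group's leading gene. DESeq2 1.42.0 was an alternative.

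Where a group had 0 UMIs of a gene, the fold was computed against 3 counts over the group and is given as a lower bound. Where it had 1 to 3, the ratio of CPM values (counts scaled to a fixed total) is given with a 95% counting interval. The named genes of the Hp against TxA23 contrasts were the 10 highest and 10 lowest folds among genes that passed the test, whose libraries did not overlap between groups and that reached a mean of 30 CPM, and up to 6 members that passed per fixed list. Those of the class contrasts were the 15 highest and 8 lowest mean folds over the 3 groups among genes past the threshold in each, without the 24 fixed markers. Anxa10, Anpep, Muc4, Cd44, Clu, Tff3, Cdx2, Aqp5, Wfdc2 and Gkn3, and Ifng, Il17a, Foxp3 and Il4 in T cells, were always named. Predicted, receptor, mitochondrial, ribosomal and sex-linked genes were left out of naming. Where few genes passed, those outside this rule are named and were chosen after their values were seen. The tests, classes, gene lists, naming rule and all alternatives but 4 were fixed before the data were examined. The plan tested lists only in metaplastic-like and T cells, Hp against TxA23. Counts of list members in pit-like cells, in the interaction and in the class contrasts were outside it, and no camera or fry result is given for them.

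The alternatives were DESeq2, its size factors in edgeR, no filter on low counts, each library left out, at most 10% mitochondrial UMIs, at least 500 genes and 1000 UMIs (shares), doublets kept, Leiden resolution 2.0, each library clustered alone, epithelial classes from the highest marker score per cell, equal cells and thinned UMIs, and mouse sex as a replicate block or, in the class contrasts, no block. The scripts were tested on simulated data drawn from the libraries' means, depths and trended dispersions with known changes. The simulated genes had no spread of their own around that trend and no correlation with each other. Recovery in the real data may therefore be lower than the rates given here. Of the genes changed by a log2 fold of 2, the test recovered 83.6% in metaplastic-like, 77.6% in pit-like, 76.1% in T and 77.6% in B cells for Hp against TxA23. The class contrasts recovered 86.6% in Hp, 91.0% in TxA23 and 95.5% in AIG, and the interaction 77.6%. At a log2 fold of 1 the recovery was 19.4% in metaplastic-like and 14.9% in T cells. The labelled sex of the 4 mouse libraries was checked against sex-linked transcripts, and 4 of 4 matched.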

Results

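Single-cell RNA sequencing from the 5′ end was performed on gastric corpus from mice infected with Helicobacter pylori (Hp, n = 2 libraries), from TxA23 mice with autoimmune gastritis (n = 2) and from patients with autoimmune gastritis (AIG, n = 3). The corpus is the acid-secreting body of the stomach, and its metaplasia is the replacement of parietal and chief cells by mucous cells. After filtering, Hp replicates 1 and 2 held 6370 and 14118 cells with medians of 10769.5 and 3940.5 UMIs per cell, and TxA23 replicates 1 and 2 held 6550 and 6128 cells with medians of 4633 and 5880. AIG replicates 1 to 3 held 3179, 2336 and 8575 cells with medians of 6114, 3954.5 and 5966 UMIs. The 2 Hp libraries differed in sex and in their labels (13MOI and 6MOI), so those factors cannot be told apart within Hp. Mouse line and disease changed together, so no comparison of Hp with TxA23 can tell them apart. Hp replicate 2 joined 6 wells of unequal depth, with medians from 1789 to 12604 UMIs per cell. The wells also differed in composition. Metaplastic-like cells ran from 0.445% to 4.924% per well, pit-like cells from 10.33% to 43.99% and T cells from 0.064% to 11.03%. Wells 4, 5 and 6 gave 220, 83 and 296 of the 609 T cells of this library. Shares of Hp replicate 2 are therefore mixtures of unlike wells, and their Wilson intervals do not cover that spread.

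The design asked which cells were present in the inflamed corpus of each disease. Metaplastic-like cells, which carry markers of mucous neck cells and of SPEM, made up 4.43% ± 3.42 of cells in Hp (SD, n = 2), 17.8% ± 2.76 in TxA23 (n = 2) and 12.2% ± 3.83 in AIG (n = 3). A cluster led by Tff2 and Gkn3 gave 109 of the 436 and 59 of the 284 metaplastic-like cells of Hp replicates 1 and 2, and 13 of the 1040 and 498 of the 1212 of TxA23 replicates 1 and 2. Pit-like cells, the mucus-secreting cells of the surface, made up 24.6% ± 1.62 in Hp, 7.79% ± 0.314 in TxA23 and 24.3% ± 7.81 in AIG. Chief-like cells, which secrete pepsinogen, were 0.722% of Hp replicate 1 (Wilson interval 0.542 to 0.962) and 15.3% of Hp replicate 2 (14.8 to 15.9). No cell of TxA23 replicate 1 was chief-like, which allows a share of up to 0.0586% by the Wilson interval, and 5 cells of TxA23 replicate 2 were. In AIG they were 5.63% ± 5.41 (11.6%, 4.11% and 1.15%). Parietal-like cells, the acid-secreting cells, were 6.60% ± 3.20 in Hp and 5.09% ± 1.62 in TxA23, and no cluster carried that name in AIG. T cells were 6.97% ± 3.75, 8.68% ± 4.40 and 11.2% ± 3.53 in Hp, TxA23 and AIG. Mast cells or basophils were 0.718% ± 0.694 in Hp and 2.42% ± 0.578 in TxA23, and tuft-like cells 1.32% ± 0.580 and 3.60% ± 1.01; in AIG these were 1.66% ± 0.715 and 0.0972% ± 0.168. Of the tuft-like cells of the mice, 1 cluster was led by Chil4 and Pga5. Squamous cells of forestomach or oesophagus were 3.74% and 0.46% in Hp and 0% and 0.0163% in TxA23. Fibroblasts were 9.15% and 4.98% against 1.76% and 1.68%, and endothelial cells 1.65% and 3.08% against 0.24% and 0.29%. Smooth muscle cells or pericytes were 4.80% and 2.42% against 0.20% and 0.88%. All shares are parts of the same total, and whether the tissue taken differed between the groups was not tested.

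With 2 against 2 libraries no exact permutation test can give a two-sided p below 1/3, so no share was tested. The metaplastic-like share was 2.01% (1.79 to 2.26) and 6.84% (6.25 to 7.49) in the Hp libraries and 15.9% (15 to 16.8) and 19.8% (18.8 to 20.8) in the TxA23 libraries. It depended on how classes were drawn: with the highest marker score per cell it was 12.5% in Hp and 30.3% in TxA23, and with each library clustered alone it was 6.90% in TxA23. Most pit-like cells of Hp replicate 2 lay in a shallow cluster led by Gkn1 and Lgals2, those of Hp replicate 1 in clusters led by Fcgbp and by Lypd8, and those of both TxA23 libraries in the Lypd8 cluster. Unnamed clusters held 14.0% ± 10.9 of the cells in Hp, 24.2% ± 16.2 in TxA23 and 9.40% ± 13.5 in AIG. The largest unnamed mouse cluster, with metaplastic markers as its best score, held 233 and 251 cells in Hp and 315 and 1519 in TxA23.

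**Figure D1:**
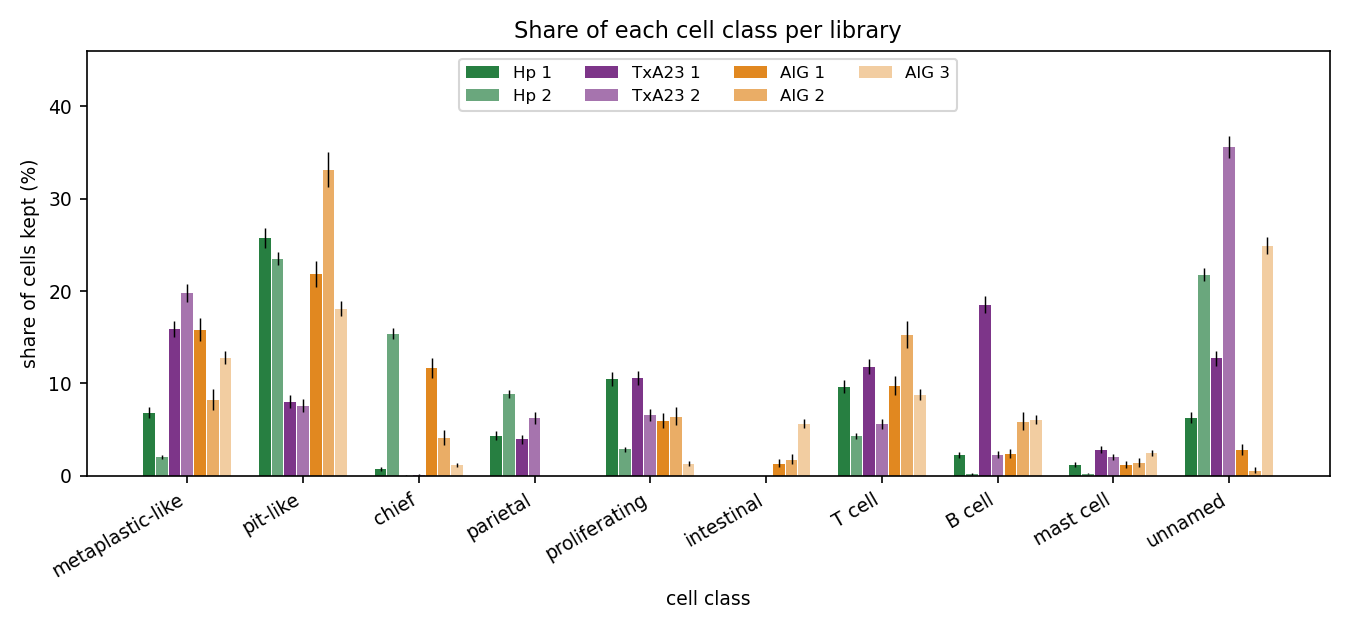
Share of the cells kept (percent, vertical axis) that fell in each cell class (horizontal axis), with 1 bar per library of Hp, TxA23 and AIG and black lines at the Wilson 95% interval. Both TxA23 bars stood above both Hp bars for metaplastic-like cells (15.9% and 19.8% against 6.84% and 2.01%) and below them for pit-like cells.

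Metaplastic-like cells were compared between Hp and TxA23 to ask whether infection and autoimmunity give the same metaplastic state. Edn2, which encodes the vasoconstrictor peptide endothelin 2, rose by a log2 fold of 3.44 ± 0.34 in Hp (SE, n = 2 against 2; adjusted p = 0.0128), and Nptx2, a secreted pentraxin, by 2.80 ± 0.27 (adjusted p = 0.0119). Ccn2, a matricellular growth factor, rose by 3.03 ± 0.37 (adjusted p = 0.0417) and was chosen after its values were seen. The lower genes in Hp were H2-Q10 (-2.15 ± 0.26; adjusted p = 0.0427), a class Ib gene of the major histocompatibility complex (MHC), its neighbours H2-Q1, Gm11127 and Gm8909, the mast cell protease gene Mcpt1 (-4.90 ± 0.51) and Gm10260 (-3.38 ± 0.26). Apart from H2-Q10 these too were chosen after their values were seen. The TxA23 libraries are labelled H2-d/b, and the H2-d haplotype differs from that of the reference genome. H2-Q1 had 0 UMIs in Hp and was at least 65.9-fold lower, Gm11127 was lower by a ratio of 733 (counting interval 131 to 28950) and Gm8909 by 144 (25.8 to 5721). Without Hp replicate 1 they were at least 16-fold, 59.2-fold and 11.7-fold lower. Edn2 (ENSMUSG00000028635) lies on chromosome 4 from 120161206 to 120167360, Nptx2 (ENSMUSG00000059991) on chromosome 5 from 144545902 to 144557478, Ccn2 (ENSMUSG00000019997) on chromosome 10 from 24595442 to 24598683, and H2-Q10 (ENSMUSG00000067235) on chromosome 17 from 35470089 to 35474563, all in GRCm38.

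In all, 9 of 12457 genes passed, 3 higher and 6 lower in Hp. DESeq2 called 201, of which 130 were higher and 71 lower, and without the cluster led by Tff2 and Gkn3 edgeR called 54 higher and 30 lower, so the balance of higher and lower genes depended on these choices. Of the genes named in advance, none passed: the log2 folds were -0.14 for Anxa10, 0.71 for Anpep, 0.77 for Muc4, 0.76 for Cd44, -0.07 for Clu, 0.58 for Tff3, 1.68 for Aqp5, -0.12 for Wfdc2 and 0.75 for Gkn3. Cdx2, the master regulator of intestinal fate, was not tested because it had 0 UMIs in Hp and 13 in TxA23. The count changed with single libraries: it was 0 without Hp replicate 1 or Hp replicate 2, 527 without TxA23 replicate 1 and 217 without TxA23 replicate 2. Without either Hp library Edn2 (3.58 and 3.31), Nptx2 (2.56 and 3.01) and H2-Q10 (-2.52 and -1.92) no longer passed, while Aqp5 passed without either TxA23 library (1.62 and 1.76) and Muc4 without TxA23 replicate 1 (1.56). With classes from marker scores 9 genes passed, 0 higher and 9 lower and 5 of them shared, so the calls of Edn2 (2.79), Nptx2 (1.74), Ccn2 and H2-Q10 (-2.24) ended. Those of Edn2 (3.51), Nptx2 (1.38) and H2-Q10 also ended with each library clustered alone.

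Fixed gene lists were tested in the same cells; no member passed over all genes, and no list was called by camera with an estimated correlation (lowest adjusted p = 0.339). Among the 8 MHC class II genes, which present antigen to helper T cells, 7 were higher in Hp when adjusted over the list alone (median log2 fold 0.93). H2-DMb1 stood at 1.95, H2-Aa at 1.09 and Cd74 at 1.02. Most genes of this list, though not Cd74, are H2 genes, and the H2-d haplotype of TxA23 differs from the reference genome. Whether this changed their mapping was not tested. The MHC class I list holds H2 genes as well. Of 30 cell cycle genes 22 were lower adjusted over the list alone (median -1.31), among them Cenpf (-2.04) and Mki67 (-1.43). A proliferating epithelial class, named by genes of this list, had been set apart by the clustering. It held 10.5% and 2.88% of cells in Hp and 10.5% and 6.56% in TxA23. The cell cycle folds thus describe the cells left in the metaplastic-like class, not proliferation of the tissue. Of 22 unfolded protein response genes 11 were higher (median 0.69), such as the chaperone genes Hspa5 (1.01) and Hyou1 (1.04). Of 22 dissociation and immediate early genes, a sign of handling stress, 16 were higher adjusted over the list alone (median 1.03), so this sign moved with the groups beside every list here. The interferon response list had 6 of 35 members higher (median 0.30), MHC class I presentation 1 of 18 (0.35), Wnt targets 2 of 16 (0.36), gastric cancer associated genes 3 of 46 (0.32), SPEM or mucous neck genes 1 of 22 (0.36) and hypoxia and glycolysis 1 of 21 (0.23). NF-kB, antimicrobial and chemokine genes had 0 of 27 (0.63) and oxidative phosphorylation 0 of 36 (-0.21).

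Camera with a preset correlation called those 12 of the 19 lists, 10 up and 2 down, and 0 with an estimated correlation. Its adjusted p was 7.38e-09 for MHC class II, 7.08e-27 for the cell cycle, 1.21e-10 for the unfolded protein response and 1.32e-22 for dissociation. These were 0.365, 0.365, 0.339 and 0.365 with an estimated correlation. Camera also gave an adjusted p of 4.84e-05 for the interferon response, 0.000276 for MHC class I, 0.00014 for NF-kB, 5.25e-05 for gastric cancer associated, 0.0155 for SPEM, 0.0308 for hypoxia, 0.00112 for Wnt target and 0.0296 for oxidative phosphorylation genes. In the same order these were 0.431, 0.431, 0.643, 0.365, 0.365, 0.373, 0.373 and 0.716 with an estimated correlation. By fry only the unfolded protein response passed (adjusted p = 0.0242). The adjusted p was 0.140 for the type 2 cytokine response, 0.512 for intestinal-type, 0.967 for parietal, 0.268 for surface mucous, 0.109 for NRF2 oxidative stress and 0.794 for cholesterol synthesis genes, none called. It was 0.999 for chief cell zymogen genes, whose median (0.68) and mean (-0.96) differed in sign and of which 2 of 9 were lower adjusted over the list alone. Without TxA23 replicate 1 camera called 14 lists, and without Hp replicate 2 it called 9, the NF-kB list then leaning the other way (adjusted p = 0.609).

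Pit-like cells, the epithelial class outside metaplasia, were compared in the same way. Gm10260 (-3.09 ± 0.24) and 9130204L05Rik (-2.85 ± 0.24) were lower in Hp, as were H2-Q1 (-7.59 ± 0.46) and Gm11127, which was at least 836-fold lower (390 and 446 without Hp replicates 1 and 2); these 4 of 12396 genes were all that passed in edgeR, and all were chosen after their values were seen. All 30 cell cycle genes were higher in Hp when adjusted over the list alone (median log2 fold 1.25), the opposite direction to metaplastic-like cells. None of them passed over all genes, of which 2155 had an unadjusted p under the threshold in edgeR. The list itself was not tested with camera or fry in pit-like cells. Cells of the proliferating class had been set apart here too. In pit-like cells MHC class II genes had a median of 1.09, with 1 of 8 higher adjusted over the list alone, type 2 cytokine response genes had 5 of 12 lower (median -0.78), and dissociation genes 3 of 22 higher (0.33). The limit on H2 genes given above holds for the MHC class II list here too. NF-kB, antimicrobial and chemokine genes had 1 of 25 higher and 3 lower (-0.24). DESeq2 called 386 genes, 221 higher and 165 lower, and the edgeR count was 0 without Hp replicate 1, TxA23 replicate 1 or TxA23 replicate 2 and 284 (187 higher, 97 lower) without Hp replicate 2.

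T cells were compared to describe the inflammation that accompanies metaplasia in each model. Of 22 measured genes of type 1 and cytotoxic T cells 7 were higher in Hp, and 15 did not pass. The median log2 fold of these 7, chosen because they passed, was 2.34. Within the T cell cluster led by Ccl5 alone none of the 7 passed (median 1.49, all positive), and within that led by Il17a none of the 5 measured (median 0.62). The cluster led by Ccl5 held 52.0% and 56.8% of the T cells in Hp and 15.8% and 15.5% in TxA23. The granzyme gene Gzma rose by a log2 fold of 3.49 ± 0.51 (2418 and 1722 CPM in Hp, 273 and 83.6 in TxA23; adjusted p = 0.00674), Gzmb by 2.41 ± 0.32 (adjusted p = 0.00463) and Gzmk by 1.93 ± 0.34, and Ifng, which encodes interferon gamma, by 2.34 ± 0.31 (279 and 347 against 53.9 and 74.0 CPM; adjusted p = 0.00493). The interleukin 12 receptor gene Il12rb2 rose by 3.17 ± 0.55, the chemokine gene Ccl5 by 1.67 ± 0.35 and Tnf by 2.68 ± 0.30 (195 and 198 against 27.7 and 35.8 CPM). Il21, a cytokine of follicular helper cells, rose by 3.20 ± 0.47. Of 16 regulatory T cell genes 8 were lower in Hp, 8 did not pass and 4 had a positive fold, and the call of the list by camera was lost (adjusted p = 0.187 with an estimated correlation). Among those lower, Il10 stood at -2.92 ± 0.35 (17.3 and 14.5 against 92.1 and 160 CPM; adjusted p = 0.00274), Ikzf2 at -1.86 ± 0.30, Izumo1r at -2.28 ± 0.36, Lrrc32 at -2.08 ± 0.44 and Foxp3, the lineage transcription factor, at -1.49 (50.6 and 39.0 against 145 and 100 CPM; adjusted p = 0.0273). Lag3, an inhibitory receptor, was lower by -3.31 ± 0.40 (64.0 and 78.0 against 453 and 965 CPM, adjusted p = 0.00304). The cluster led by Il17a was the T cell cluster with less Cd8a, and its name gives a leading gene only. Over all T cells Il17a stood at 664 and 2380 CPM in Hp and at 432 and 43.0 CPM in TxA23. The cluster led by Il17a held 48.0% and 43.2% of the T cells in Hp and 84.2% and 84.5% in TxA23. Whether this shift of clusters accounts for part of the lower regulatory T cell genes and Lag3 was not weighed. Gzma (ENSMUSG00000023132) lies on chromosome 13 from 113093825 to 113100981, Ifng (ENSMUSG00000055170) on chromosome 10 from 118441046 to 118445892, Il10 (ENSMUSG00000016529) on chromosome 1 from 131019845 to 131024974 and Lag3 (ENSMUSG00000030124) on chromosome 6 from 124904361 to 124911705 in GRCm38.

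In T cells 184 of 9074 genes passed, 75 higher and 109 lower in Hp, and 121 of these were also called by DESeq2. The balance turned with the tool and the library: DESeq2 called 95 higher and 80 lower, edgeR without a filter on low counts 397 and 306, and 54.7% to 58.6% of the calls were higher with 1 library left out. The other named higher genes were Trat1 (2.96), Qpct (3.01), Actn2 (2.85), Dnajb1 (1.82) and Ncr1 (2.84), a marker of natural killer cells. Of other markers of these cells Klrb1c (1.24), Klre1 (1.46) and Eomes (-0.02) did not pass. The other named lower genes were Ptpn5 (-4.04), Axl (-3.77), Angptl2 (-3.68), Nrn1 (-3.58), Cd200 (-1.80), Il1r1 (-1.68), Tnfrsf9 (-1.64), Nrp1 (-1.61), Tox (-1.28) and Havcr2 (-1.27), with Ccl9 at least 60.8-fold lower and Slc37a2 lower by a ratio of 42.0 (13.9 to 207). For Ccl9 this bound was 30.4 without either Hp library, 234 without TxA23 replicate 1 and 25.5 without TxA23 replicate 2; for Slc37a2 the ratio was 63.0 without Hp replicate 1 and 75.1 without TxA23 replicate 1. Il17a, the signature cytokine of Th17 cells, stood at 664 and 2380 CPM in Hp and 432 and 43.0 in TxA23 (log2 fold 2.62; adjusted p = 0.124). Il4 did not pass (0.50; adjusted p = 0.637). Transcripts of other cells also moved with the groups: Muc5ac (3.02) and Mucl3 (3.63) of pit cells were higher in Hp, and Mcpt1 (-5.93) and Mcpt2 (-5.02) of mast cells, Chil4 (-4.34) and Bpifb1 (-3.55) were lower. The count was 510 without Hp replicate 1, 265 without Hp replicate 2, 1029 without TxA23 replicate 1 and 450 without TxA23 replicate 2, with 163, 144, 155 and 182 genes shared with the full comparison. Foxp3 no longer passed without Hp replicate 2 (-1.30; adjusted p = 0.0883). Calls also ended for Nrp1 (-1.35) and Tox (-1.23) without Hp replicate 2, for Il1r1 (-1.41), Tnfrsf9 (-1.47), Tox (-1.32) and Havcr2 (-1.04) without Hp replicate 1 and for Il1r1 (-1.56) without TxA23 replicate 1. Il17a passed without Hp replicate 1 (3.27), TxA23 replicate 1 (5.14) or TxA23 replicate 2 (1.82), and with mouse sex as a block (2.86; adjusted p = 0.0257). Without TxA23 replicate 1 Gzma was 4.63 and Il21 2.37, without TxA23 replicate 2 Lag3 was -2.67, and Lrrc32 was -3.13 and -1.47 without Hp replicates 1 and 2.

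**Figure D2:**
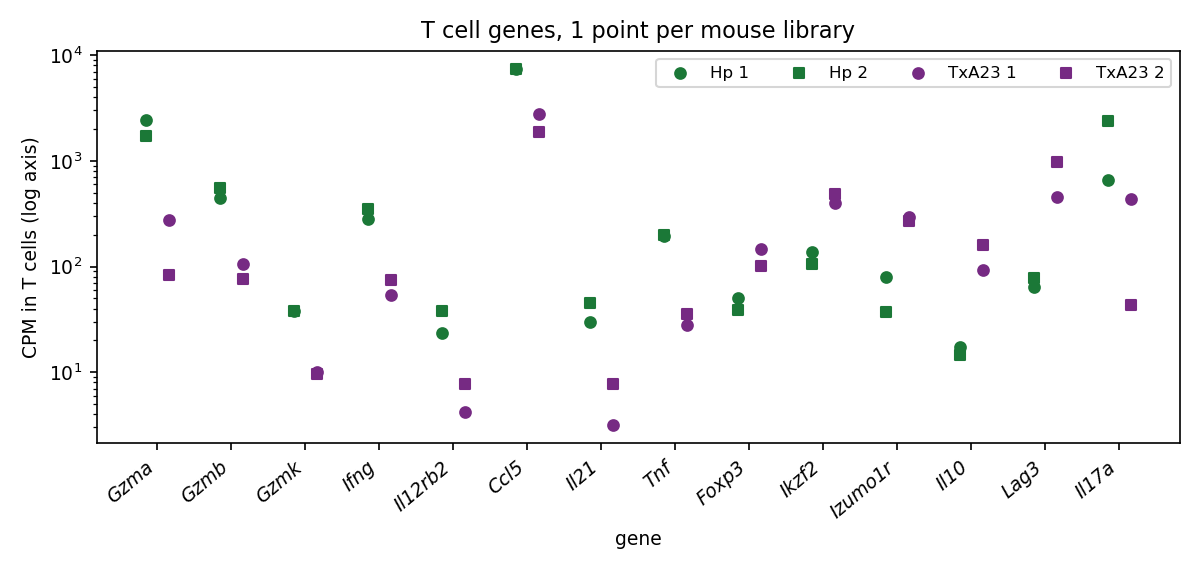
Level of named T cell genes (TMM-scaled CPM, log axis, vertical) in the summed T cells of each mouse library, with 1 point per library and values under the level of 3 counts drawn at that level. The Hp points of Gzma, Gzmb and Ifng lay above both TxA23 points, and those of Il10, Ikzf2 and Lag3 below them.

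Of the 22 measured Th1 and type 1 cytotoxic genes 7 rose, and 10 rose and 2 fell adjusted over the list alone, the latter being the perforin gene Prf1 (-1.30) and Ccl3 (-1.82). The median was 0.90, and the camera adjusted p was 3.67e-07, or 0.187 with an estimated correlation. Of 16 regulatory T cell genes 8 fell, 10 adjusted over the list alone (median -1.20; camera adjusted p = 1.94e-09), with an adjusted p = 0.187 with an estimated correlation and 0.0222 by fry. T follicular helper genes had 1 member higher and 2 lower of 11, or 1 and 5 adjusted over the list alone (camera adjusted p = 0.0308, and 0.567 with an estimated correlation). Exhaustion or chronic activation genes had 4 lower of 15 (camera adjusted p = 0.0353, and 0.695 with an estimated correlation), with a median of -0.02 and a mean of -0.43. Dissociation genes, the sign of handling stress, had 9 of 22 higher adjusted over the list alone (median 0.79; camera adjusted p = 3.72e-07, and 0.567 with an estimated correlation). No member passed among 30 interferon response genes (median 0.52; camera adjusted p = 0.00904) or 29 cell cycle genes (-0.54; 0.00229), both with an adjusted p = 0.695 with an estimated correlation.

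Camera did not call the Th17 list, in which 4 of 16 members were higher and 5 lower adjusted over the list alone (median 0.16, mean -0.04; adjusted p = 0.710), nor Th2 (0.198), naive or central memory T (0.393), hypoxia and glycolysis (0.631), unfolded protein response (0.147), oxidative phosphorylation (0.710) or cholesterol synthesis (0.228). It called 7 of the 14 lists, 3 up and 4 down, and none with an estimated correlation. The count was 5 without Hp replicate 1 or TxA23 replicate 1, 7 without Hp replicate 2 and 8 without TxA23 replicate 2.

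TxA23 mice carry a transgenic T cell receptor, so the use of receptor variable genes was examined. Trbv1 was the most abundant Trbv gene in 63.0% of the T cells of TxA23 replicate 1 with any Trbv UMI (327 of 519; Wilson interval 58.8 to 67.1) and in 78.8% of those of TxA23 replicate 2 (26 of 33; 62.2 to 89.3), against 22.0% (18.3 to 26.2) and 20.6% (17 to 24.7) in Hp. Trav14d-3-dv8 led among Trav genes in 29.0% (23.7 to 35.0) and 61.5% (35.5 to 82.3) of TxA23 T cells with any Trav UMI, the latter 8 of 13 cells, and in 0.385% and 1.21% in Hp. Among cells with at least 2 Trav UMIs it led in 16% (9.40 to 25.9) of TxA23 replicate 1 and in 2 of 3 cells of TxA23 replicate 2; the share for Trbv1 was 56.4% and 2 of 3 cells. A Trbv1 UMI was found in 51.0% and 7.63% of all T cells in TxA23 and in 1.33% and 0.431% of pit-like cells, where medians were 24463 and 11961 UMIs per cell against 1884 and 878 in T cells. Trbv UMIs were detected in 67.2% of the T cells of TxA23 replicate 1 and in 9.68% of those of TxA23 replicate 2, so the second share rests on few cells. In T cells of TxA23 replicate 2, 46 UMIs of beta variable genes stood against 431 of beta constant genes. In TxA23 replicate 1 these were 1627 and 2096, so the variable part was read less often in replicate 2. A Trav14d-3-dv8 UMI was found in 10.8% and 2.35% of all T cells of TxA23 replicates 1 and 2 and in 0% and 0.647% of their pit-like cells. Trav8n-2 led in 0 of 260 cells of Hp replicate 1 and in 18.4% (14.6 to 23) of Hp replicate 2, so its share in Hp came from 1 library. No test was made with 2 against 2 libraries.

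**Figure D3:**
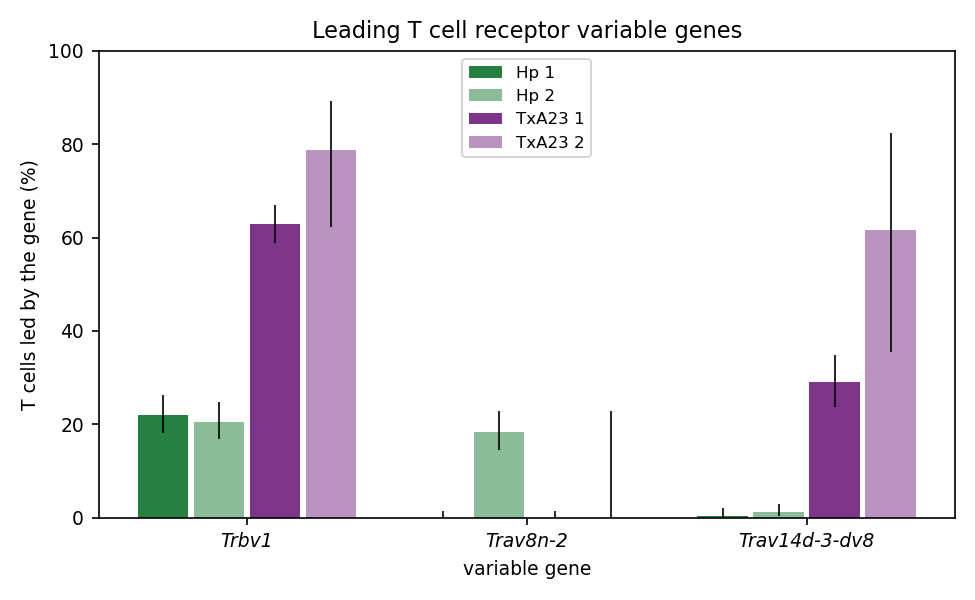
Share of the T cells with a Trbv or Trav UMI (percent, vertical axis) whose most abundant such gene was Trbv1, Trav8n-2 or Trav14d-3-dv8 (horizontal axis), with 1 bar per mouse library and black lines at the Wilson 95% interval. Trbv1 stood at 63.0% and 78.8% in TxA23 and at 22.0% and 20.6% in Hp.

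B cells were few in Hp (142 and 28 cells) against 1212 and 140 in TxA23, and 6 of 2723 genes passed. Pigr (-3.08 ± 0.60), the polymeric immunoglobulin receptor of epithelium, Bpifb1 (-3.12 ± 0.59), Gm10260 (-3.04 ± 0.50), Mcpt1 (at least 12.4-fold) and Mcpt2 (at least 10.3-fold) were lower in Hp, and the light chain gene Iglv3 was higher (2.34 ± 0.42); Gm10260 and Iglv3 were chosen after their values were seen. Pigr, Bpifb1 and the Mcpt genes are markers of epithelial and mast cells, not of B cells. DESeq2 called 0 genes, none passed with mouse sex as a block, and 279 had an unadjusted p under the threshold in edgeR. The count was 33, 37 and 28 without Hp replicate 1, Hp replicate 2 and TxA23 replicate 1, and 0 without TxA23 replicate 2, without which Mcpt1, Mcpt2, Bpifb1 and Pigr did not pass; Mcpt1 and Pigr were also lost without Hp replicate 1. Without that library the bounds were 1.84-fold for Mcpt1 and 1.52-fold for Mcpt2.

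The design isolated metaplastic cells by signature, and the contrast of metaplastic-like with pit-like cells was set side by side in the 3 diseases. Among Wnt target genes, which mark stem and progenitor cells, Lgr5, the stem cell receptor, rose by 9.90 ± 0.33 in Hp, 6.65 ± 0.35 in TxA23 and 3.55 ± 0.60 in AIG, Sp5 by 6.62, 5.77 and 4.02, and Notum by 6.73 in Hp and 5.54 in AIG, with a ratio of 49.3 (13.4 to 411) in TxA23 (32.0 without TxA23 replicate 1). Lgr5 had 4 UMIs in the pit-like cells of Hp and 5 in those of TxA23, so its folds there rest on few counts. Their SE may understate the error, and the 2 sizes cannot be ranked. In metaplastic-like cells Lgr5 had means of 57.5 CPM in Hp and 28.5 in TxA23. The tight junction gene Cldn2 rose by 8.15, 6.20 and 3.43, and the interferon-induced chemokine gene Cxcl9 by 4.42, 6.01 and 5.92. Lcn2, an antimicrobial protein of neutrophils and inflamed epithelium, rose by 7.84, 6.77 and 1.59, and the sodium exchanger gene Slc9a3 by 8.88, 5.13 and 2.07. The matrix protease gene Mmp7 had a ratio of 540 (147 to 4503) in Hp, was at least 267-fold higher in TxA23 and rose by 6.19 ± 0.44 in AIG. Without TxA23 replicate 1 the bound for Mmp7 in TxA23 was 10.9-fold, and in Hp Mmp7 was at least 144-fold higher without Hp replicate 1 and had a ratio of 302 without Hp replicate 2. In AIG Lgr5 was 2.38 without AIG replicate 3 and 4.49 without AIG replicate 2, and Mmp7 5.26 and 6.99. CXCL9 had 38, 1 and 629 UMIs in metaplastic-like cells of AIG replicates 1 to 3 and was not tested without replicate 1 or 3, for too few counts. Krt20, a keratin of mature surface cells, fell to log2 folds of -5.59 ± 0.47, -6.76 ± 0.42 and -5.92 ± 0.24, as did the alcohol dehydrogenase gene Adh7 (-6.13, -4.30 and -6.37) and the iodide transporter gene Slc5a5 (-6.45, -4.35 and -5.75). In the mice these genes varied with the library left out: Cxcl9 in Hp was 6.39 without Hp replicate 1 and 2.92 without Hp replicate 2, Lcn2 9.86 and 6.00, and Notum 5.54 and 8.24. In TxA23 the folds without TxA23 replicate 1 were 5.49 for Lgr5, 5.62 for Lcn2, -5.77 for Krt20, -2.60 for Adh7 and -2.79 for Slc5a5, and without TxA23 replicate 2 they were 7.59 for Lgr5, -7.73 for Krt20, -6.30 for Adh7 and -6.58 for Slc5a5. Lgr5 (ENSMUSG00000020140) lies on chromosome 10 from 115450311 to 115587780, Mmp7 (ENSMUSG00000018623) on chromosome 9 from 7692090 to 7699585 and Krt20 (ENSMUSG00000035775) on chromosome 11 from 99428403 to 99438150 in GRCm38.

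Genes fixed in advance were compared in each disease. Anpep, an intestinal brush border peptidase, rose in metaplastic-like cells of Hp (5.25 ± 0.31) and TxA23 (4.76 ± 0.34) but was lower in AIG (-2.27 ± 0.67; adjusted p = 0.0299), where it had 19 UMIs in metaplastic-like and 74 in pit-like cells and ANPEP stood at -3.98 without AIG replicate 3. Anxa10 was lower in Hp (-1.73 ± 0.15) and TxA23 (-1.56 ± 0.15) and did not pass in AIG (-0.32; adjusted p = 0.224). Cd44, a stem cell and SPEM marker, rose by 3.26, 2.25 and 3.07 in Hp, TxA23 and AIG, Aqp5 by 8.21, 5.71 and 4.71, Wfdc2 by 2.47, 2.14 and 2.77, Clu by 1.45, 0.83 and 2.79, and Gkn3 by 7.86 and 4.81 in the mice, all 5 being markers used to name the class, which favours a rise. Muc4 (0.42, -0.83 and -0.56) and Tff3 (-0.62, -1.30 and -0.57) did not pass in any group. ANXA10 passed without AIG replicate 3 (-0.26), TFF3 without AIG replicate 1 (-1.10) and MUC4 without AIG replicate 2 (-0.85). Muc4 in Hp passed upward without Hp replicate 1 (1.65) and turned to -0.76 without Hp replicate 2, and in TxA23 it passed at -0.84 without either Hp library. Clu in Hp missed the threshold without Hp replicate 1 (1.21; adjusted p = 0.0532).

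The other genes of the naming rule that rose in each group were Cd177 (7.43 in Hp and 4.67 in TxA23, ratio 37.1 in AIG, 12.4 to 182), Nkd1 (6.82, ratio 117 with 32.3 to 974, and 3.50) and Sbspon (6.87, ratio 97.2 with 33.0 to 473, and 3.23). Gp2 was at least 16.4-fold higher in Hp and at least 49.5-fold in TxA23, and rose by 2.92 in AIG. Adamtsl3 had a ratio of 260 (69.4 to 2184), was at least 21.6-fold higher and rose by 2.93. Faim2 had a ratio of 147 (23.7 to 6096), was at least 7.87-fold higher and rose by 3.76. Ccdc136 was at least 16.4-fold and at least 8.55-fold higher and rose by 2.88. Those that fell were Mucl3 (-6.55, -4.83 and -4.42), Fer1l6 (-6.51, -5.40 and -3.01), B3galt5 (at least 8.64-fold lower, a ratio of 23 with 5.84 to 198, and -3.50), Cidec (a ratio of 55.2 with 15.2 to 457, -5.85, and a ratio of 40 with 10.6 to 338) and Scnn1b (ratios of 21.9 with 3.88 to 872 and of 20.7 with 3.16 to 877, and -6.28). Single libraries decided some of these: without Hp replicate 1, Gp2 (adjusted p = 0.163), Faim2 (0.0762), Ccdc136 (0.0505), B3galt5 (0.566) and Scnn1b (0.836) did not pass in Hp, nor did Ccdc136 (0.112) without Hp replicate 2. Without TxA23 replicate 1, Gp2 (0.0713), Faim2 (0.184) and Scnn1b (0.0953) did not pass in TxA23, nor Faim2 (0.0731) and Ccdc136 (0.0644) without TxA23 replicate 2. LCN2 did not pass in AIG without AIG replicate 1 (1.37; adjusted p = 0.0687). Bounds and ratios from few UMIs moved as well. Without Hp replicate 1 they were 4.5-fold for Gp2, 81.0 for Adamtsl3, 13.5 for Faim2 and 18.4 for Cidec in Hp, and B3galt5 and Scnn1b, with 6 and 1 UMIs left in pit-like cells, allowed no bound above 1. Without Hp replicate 2 they were 9.89 for Gp2, 138 for Adamtsl3, 89.0 for Faim2, 4.94 for Ccdc136 and 106 for Cidec. Without TxA23 replicate 1 they were 6.62 for Gp2, 8.28 for Adamtsl3, 2.39 for Faim2, 46.9 for Nkd1, 37.0 for Sbspon and 10.9 for Scnn1b in TxA23, and Ccdc136 allowed no bound above 1. Without TxA23 replicate 2 they were 13.0 for Adamtsl3, 201 for Nkd1, 228 for Sbspon, 5.23 for B3galt5 and 3.49 for Scnn1b. CD177 in AIG had ratios of 63.9 and 20.5 without AIG replicates 2 and 3.

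**Figure D4:**
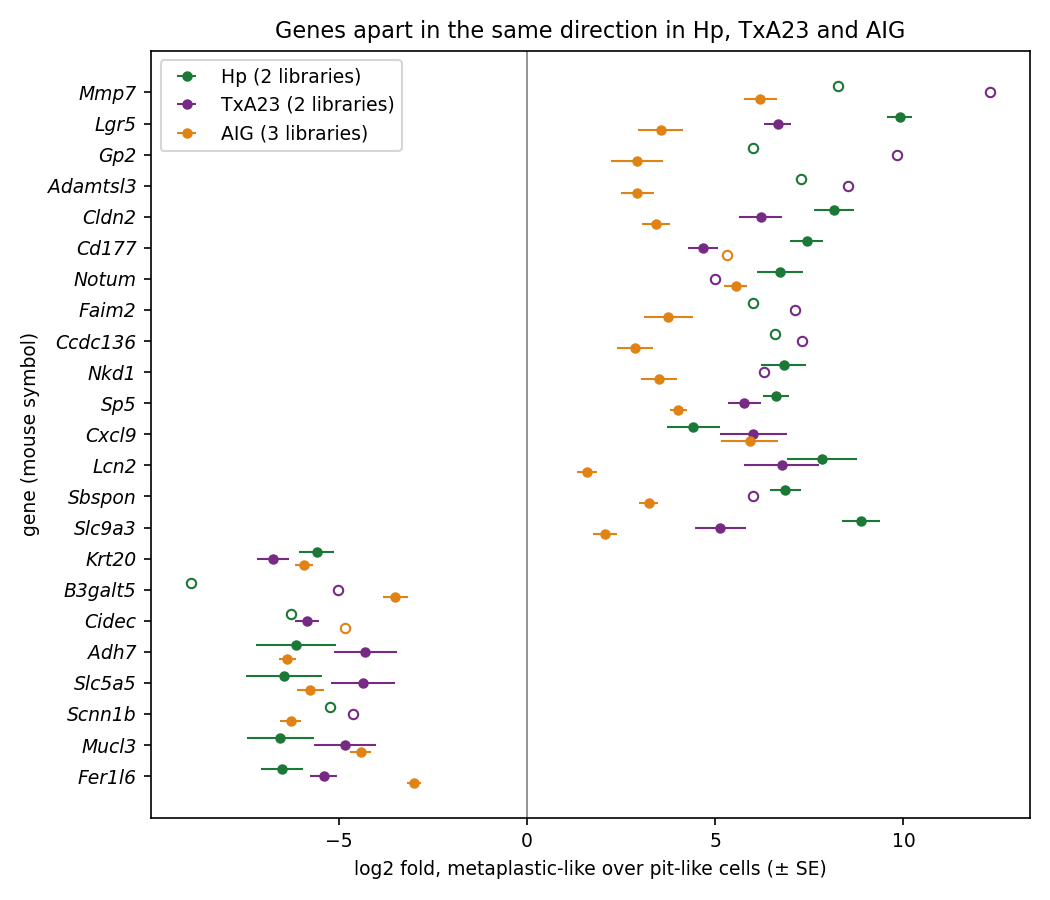
Log2 fold of metaplastic-like over pit-like cells (horizontal axis) for the genes of the naming rule (vertical axis) in Hp, TxA23 and AIG, with lines of 1 SE to each side. Open points have at most 3 UMIs in the lower class, so that their fitted fold depends on the prior count and no SE is drawn. Lgr5 stood at 9.90, 6.65 and 3.55, with 4 and 5 UMIs in the pit-like cells of Hp and TxA23. Krt20 stood at -5.59, -6.76 and -5.92.

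In the gene groups of this contrast, Wnt targets had 14 members higher and 1 lower of 16 in Hp, 14 and 1 in TxA23 and 13 and 1 in AIG. MHC class II genes had 7 higher of 8 in Hp and in TxA23 and 2 of 3 in AIG, none lower. NF-kB, antimicrobial and chemokine genes had 18 higher and 1 lower of 28 in Hp, 15 and 7 in TxA23 and 18 and 6 of 27 in AIG. Surface mucous genes, which include the markers that named the pit-like class, had 13 of 15 lower in Hp, 15 in TxA23 and 10 of 12 in AIG, and chief cell zymogen genes had 8 of 9, 9 of 9 and 4 of 11 higher. NRF2 oxidative stress genes had 22 of 25, 21 of 25 and 12 of 20 lower, and cholesterol synthesis genes 20 of 21, 19 of 21 and 11 of 20. Oxidative phosphorylation genes had 31 and 28 of 36 lower in Hp and TxA23 and 1 of 27 in AIG. Cell cycle genes fell in Hp (30 of 30), whereas 6 of 30 were higher in TxA23 and 4 of 28 lower in AIG, with the proliferating class set apart in each. Gastric cancer associated genes went both ways, with 16 higher and 17 lower of 46 in Hp, 12 and 20 in TxA23 and 12 and 15 of 42 in AIG, as did parietal genes (5 and 2 of 14, 6 and 2 of 14, and 9 and 2 of 13). Intestinal-type genes had 2 higher and 4 lower of 14, 2 and 6 of 14, and 1 and 10 of 15, and SPEM or mucous neck genes, which include markers that named the class, 17 and 3 of 23, 15 and 3 of 23, and 10 and 3 of 21. Interferon response genes had 14 higher and 5 lower of 35, 15 and 9 of 35, and 6 and 7 of 22, MHC class I genes 4 and 1 of 18, 0 and 1 of 18, and 2 and 1 of 12, and type 2 cytokine response genes 2 and 5 of 10, 1 and 6 of 10, and 1 and 2 of 4. Hypoxia and glycolysis genes had 3 higher and 14 lower of 21, 0 and 18 of 21, and 2 and 6 of 20, and unfolded protein response genes 12 and 1 of 22, 6 and 3 of 22, and 0 and 2 of 22. Dissociation genes had 5 higher and 2 lower of 22 in Hp, 2 and 8 in TxA23 and 9 and 0 in AIG.

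In all, 5629 of 12922 genes passed in Hp (2636 higher), 4982 in TxA23 (2307 higher) and 4677 of 14078 in AIG (2233 higher). No gene passed the test of a difference between Hp and TxA23 in edgeR, where 1786 had an unadjusted p under the threshold, and DESeq2 called 282. Over the cell cycle list alone 30 of 30 genes passed this test, lower in Hp (median -2.50), in cells from which the proliferating class had been set apart. Adjusted over each list alone, members were higher in Hp in the NF-kB (8 of 28), gastric cancer associated (9 of 46), hypoxia (7 of 21), SPEM (5 of 23), dissociation (4 of 22), NRF2 (3 of 25) and surface mucous (2 of 15) lists, and type 2 cytokine response genes had 4 higher and 1 lower of 10. Without 1 library the interaction gave 173 genes (Hp replicate 1), 112 (Hp replicate 2), 205 (TxA23 replicate 1) and 2 (TxA23 replicate 2). The count in Hp was 3108 without Hp replicate 1, that in TxA23 2052 without TxA23 replicate 1 and 2731 without TxA23 replicate 2, and that in AIG 2787 without AIG replicate 1.

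Of 10098 genes tested in all 3 groups, 251 passed with a log2 fold above 1 in each, against 9.63 for independent lists, and 226 passed below -1 in each, against 6.91. Of the 251, 11 were markers used to name the classes, as were 8 of the 226. Higher in pairs of groups were 835 genes of Hp and TxA23 (131 for independent lists), 315 of Hp and AIG (85.8) and 301 of TxA23 and AIG (83.3). The Hp and TxA23 classes came from a joint clustering and a joint fit, and the AIG classes from partly the same markers. An excess over independent lists was therefore favoured in advance. No library was of healthy tissue, so an overlap particular to metaplasia cannot be told from that of mucous neck with pit cells. Across genes, which are not independent replicates, the Spearman correlation of folds was 0.763 between Hp and TxA23, 0.226 between Hp and AIG and 0.315 between TxA23 and AIG. Metaplastic-like cells of AIG replicate 3 came from a cluster led by OLFM4 and REG3A and those of AIG replicates 1 and 2 from a cluster led by LCN2 and CXCL3, and AIG replicate 3 had been counted with another Cell Ranger version.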

Additional observations from a re-analysis of the deposited data

Results flagged for a closer look

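Anpep moved in opposite directions in the 2 species. In every Hp and TxA23 library its level was higher in metaplastic-like than in pit-like cells, and in every AIG library it was lower. The mean log2 fold per library was 5.66 ± 0.02 in Hp (SD, n = 2), 5.25 ± 1.18 in TxA23 (n = 2) and at most -2.14 in AIG (n = 3), where ANPEP had 0 and 2 UMIs in the metaplastic-like cells of AIG replicates 1 and 2 and was set to 3 counts. The difference was therefore at least 7.80 between Hp and AIG and at least 7.39 between TxA23 and AIG. Neither difference was tested, and in AIG the fold rested on 19 and 74 UMIs.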

How the results depend on the processing

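Of the values for single genes and lists, 2101 kept their direction and their side of the threshold under the alternatives fixed in advance, 192 kept their direction but no longer passed, 27 newly passed, 32 moved and 19 turned. Of the counts and shares, 116 stayed and 80 moved. Alternatives chosen after seeing the data were the deep wells of Hp replicate 2, unnamed clusters added, each T cell cluster alone and the classes without the cluster led by Tff2 and Gkn3; of their values 314 and 17 stayed, 39 no longer passed, 3 newly passed and 5 moved. B cells and the AIG contrast could not be fitted with each library clustered alone, because a sum fell under 25 cells or left no residual degrees of freedom. Where a library was left out of a group of 2, the lone library was assumed to vary like the other group. The cause of the changes below was not tested. At a log2 fold of 1 the test found 19.4% of simulated changes in metaplastic-like cells, so most changes of that size would be missed.

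For the comparison of Hp with TxA23 the count of genes, 9 in metaplastic-like, 4 in pit-like, 184 in T and 6 in B cells, moved as follows. With DESeq2 it was 201 in metaplastic-like, 386 in pit-like and 0 in B cells, and with no filter on low counts 598, 535, 703 in T and 38 in B cells. Leaving out 1 library gave 0 to 527 in metaplastic-like, 0 to 284 in pit-like, 265 to 1029 in T and 0 to 37 in B cells. At most 10% mitochondrial UMIs gave 26 in metaplastic-like cells, doublets kept 14 there and 109 in T cells, Leiden resolution 2.0 gave 25, and each library clustered alone 0 in metaplastic-like and 1 in pit-like cells. Equal cells and thinned UMIs gave 19 in metaplastic-like, 19 in pit-like, 111 in T and 0 in B cells. Adding unnamed clusters gave 19 and leaving out the cluster led by Tff2 and Gkn3 gave 84 in metaplastic-like cells. The T cell cluster led by Ccl5 alone gave 10 and that led by Il17a alone 45.

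With mouse sex as a replicate block the count was 12 in pit-like, 531 in T and 0 in B cells. No label says that the numbers mark shared animals, and the deviations of same-numbered libraries from their group means correlated at -0.0357 in metaplastic-like, 0.0937 in pit-like, 0.101 in T and 0.0389 in B cells, so the libraries were not treated as pairs. Il17a passed with this block (2.86; adjusted p = 0.0257).

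For metaplastic-like against pit-like cells the count was 1466 in Hp and 286 in TxA23 with each library clustered alone, and 349 in AIG with no replicate block. Leaving out 1 library gave 3108 to 5211 in Hp, 2052 to 5650 in TxA23 and 2787 to 5343 in AIG. The difference between Hp and TxA23, with 0 genes, gave 282 with DESeq2, 702 with no filter on low counts, 2 to 205 with 1 library left out, 102 with doublets kept, 6 with Leiden resolution 2.0, 129 with equal cells and thinned UMIs and 73 without the cluster led by Tff2 and Gkn3. The lists called fell from 12 in metaplastic-like and 7 in T cells to 0 and 0 with an estimated correlation and 1 and 1 with fry, and were 9 to 14 and 5 to 8 with 1 library left out. The 251 shared genes became 435 with a log2 fold above 0, 103 above 2 and 155 to 258 with 1 library left out.

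The metaplastic-like share was 11.3% in Hp and 34.2% in TxA23 with at least 500 genes and 1000 UMIs. With marker scores it was 12.5%, 30.3% and, in AIG, 8.07%. In TxA23 it was 22.7% with at most 10% mitochondrial UMIs, 21.9% with Leiden resolution 2.0 and 6.90% with each library clustered alone; with doublets kept it was 23.6% in TxA23 and 7.11% in AIG. The pit-like share in Hp and TxA23 was 19.3% and 6.04% with at most 10% mitochondrial UMIs, 14.5% and 4.18% with at least 500 genes and 1000 UMIs, 19.4% and 6.37% with doublets kept, 16.6% and 3.22% with Leiden resolution 2.0 and 18.6% and 10.6% with each library clustered alone. With marker scores it was 15.3% in TxA23. The T cell share in AIG was 5.98% with Leiden resolution 2.0.

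Values that turned belonged almost all to genes that had not passed. With 1 library left out, log2 folds in metaplastic-like cells ran from -1.40 (without Hp replicate 1) to 1.47 for Tff3, which was -0.02 without TxA23 replicate 1, from -0.42 to 0.42 for Clu (0.09 without Hp replicate 2), from -0.36 to 0.10 for Wfdc2 (0.09 without TxA23 replicate 1) and from -0.37 to 0.15 for Anxa10, which was 0.017 with marker scores. In T cells Il4 ran from -0.45 to 1.08 and was -0.49 with Leiden resolution 2.0 and -0.31 with each library clustered alone. Muc4 in Hp ran from -0.76 to 1.65 and was -0.19 with at most 10% mitochondrial UMIs, -0.0926 with doublets kept and -0.23 with each library clustered alone. In AIG MUC4 turned to 0.19 with at most 10% mitochondrial UMIs and 0.00861 with marker scores, and TFF3 to 0.31 with marker scores. The adjusted p of the NF-kB, antimicrobial and chemokine list in metaplastic-like cells, Hp against TxA23, ran from 1.94e-16 to 0.609, the latter without Hp replicate 2, where the list turned.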

Other observations

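Cym, which encodes the milk-clotting protease chymosin, was among the leading genes of 2 metaplastic-like clusters. Cym stood at 4890 and 465 CPM in the metaplastic-like cells of TxA23 and at 4.59 and 0.33 CPM in those of Hp, and at 1760 and 284 CPM in the parietal-like cells of TxA23. It was chosen after its values were seen and did not pass (adjusted p = 0.0784).

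In AIG, intestinal-like cells made up 2.90% ± 2.36 of cells (SD, n = 3), in a cluster led by FABP1, RBP2 and APOA4 and another led by MUC2, SPINK4 and TFF3. An unnamed cluster led by SCGB3A1, SFTPC and SFTPB, genes of airway and lung epithelium, was found in all 3 AIG libraries. Plasma cells were 5.77% of cells in AIG, 1.04% in Hp and 1.43% in TxA23. The ratio of variable to constant region UMIs in receptor transcripts was lower in TxA23 replicate 2 than in any other mouse library. It was 0.107 for T cell receptor beta against 1.69, 2.43 and 0.776, and 0.062 for alpha against 1.28, 2.29 and 0.4345. For immunoglobulin kappa it was 0.562 against 9.23, 13.5 and 3.60, and for immunoglobulin heavy chain 0.0244 against 1.66, 2.59 and 0.492.

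Both tests of the first pattern were chosen after the result was seen. Of 7 genes lower in Hp in metaplastic-like or pit-like cells, 4 lay among the H2 genes of chromosome 17, as did 126 of 13078 tested genes (one-sided Fisher's exact p = 2.81e-07); the region was drawn because H2 genes had been seen among the 7, so this p does not count for a line variant that changes mapping, which stays open. Free RNA from another cell type was argued against as the whole cause, since 2 of the 7 genes were over 10 times higher in 1 class, and for 9130204L05Rik that class was the pit-like class in which it was lower. It could account for Mcpt1, highest in mast cells. Summed over all classes, Gm11127 had 6 UMIs in Hp and 5474 in TxA23, H2-Q1 10 and 1563, and Gm8909 9 and 1130. H2-Q10 had 799 and 3095. Mouse line, disease and the MOI or MOA labels differ together between Hp and TxA23. A line difference and a biological difference between infection and autoimmunity therefore cannot be told apart, and the latter stays open as untested.

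Of the tests of the second pattern, the fit of each T cell cluster alone was chosen after the pattern was seen. Of 22 type 1 and cytotoxic genes 7 were higher in T cells of Hp and 15 did not pass (median log2 fold 0.90; adjusted p = 0.187 with an estimated correlation), and the median of the 7, chosen because they passed, was 2.34. Fitted alone, the Ccl5 cluster gave a median of 1.49 over 7 genes and the Il17a cluster 0.62 over the 5 measured, with 0 called in each, so a larger share of the Ccl5 cluster in Hp could account for part of the pattern and stays open. Free RNA was argued against only for the genes highest in T cells, since 1 of 7, Gzmb, was highest in another class. The list was made of T cell genes, which favours this outcome, and no cluster was named as natural killer cells. With equal cells and thinned UMIs the median of the 6 genes measured was 2.27 and 5 passed. This argued against unequal depth for those genes only, which had been chosen in the same counts. The difference between infection and autoimmunity that the design names stays open as untested.

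The third pattern was picked after values had been seen, in place of one on the receptor ratios above; its test of Pdx1 and Nkx6-3 was set before the values of these genes were seen and the other 2 tests after. The metaplastic-like cluster led by Tff2 and Gkn3 held 1.71% and 0.418% of cells in Hp and 0.198% and 8.13% in TxA23. Antral tissue may be its source: the antral genes Pdx1 and Nkx6-3 were higher there in 3 of 3 libraries (128 against 30.8, 102 against 54.3 and 111 against 3.96 CPM), and the libraries with the larger shares were 2 of 2 with the higher Gast in endocrine cells. Disease state alone was argued against, since the TxA23 shares differed by a ratio of 40.9 and the Hp shares by 4.09. Pseudopyloric metaplasia, in which corpus glands take on antral features, stays open.

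Other splits of the sums were counted for the class contrast, a test chosen before the result was seen. Over both mouse groups 1 of 32 splits gave a count as large as the 6390 genes of the real one, and the highest other gave 0. The classes were drawn from the same counts, which favours the real split, so this says nothing about chance. In AIG 1 of 10 splits reached 4677 genes, the highest other gave 0, and the splits are too few to tell.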
